A study of Homo sapiens with 8 samples.

How the data were processed

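Progesterone receptor ChIP-seq was deposited for primary HUVECs infected at passage 4 with a lentivirus for the human receptor. Per the labels' protocols, cells were grown in serum stripped of steroids, treated 3 days after confluence with 100 nM progesterone for 1 h, crosslinked, and sonicated to fragments of about 200 bp, and 3 µg of antibody was used per precipitation. The series has 8 libraries, 1 per group. For 2 control libraries the titles and the antibody labels name different antibodies. Groups follow the titles, and no value of either control was used by itself.

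Reads were aligned to hg19, and Bowtie 0.12.7, MACS 1.3.7.1 and HOMER are named in the submitters' processing notes, which give no role or order for them. Read filtering and the number of reads per library are not given in the sources used here. Peaks were called for each library by itself against 1 control at a time. The sheet labels number the libraries, with C1 the vehicle and C2 the progesterone ChIP by the sample each file belongs to. Which libraries C3, C4, C5 and C6 stand for is not given in the sources used here.

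Each deposited peak has a start, an end and a score, and the score is that of the authors' peak caller against the named control, on a scale of -10 times log10 of p. The lowest score in the deposited lists was 50, which on this scale is a p of 1e-05. The final lists were compared with the lists per control. All final peaks were peaks of the list against C4 with the same position and score, and overlapped peaks of the other 2 lists. Of the peaks that met this, 3 with vehicle and 64 with progesterone were not in the final list, by a rule that is not given in the sources used here. Scores of the final lists are therefore scores against C4. Per the file headers, the authors assigned peaks to the nearest gene within 50 kb with GREAT 2.0.2 for vehicle and GREAT 2.0.1 for progesterone on hg19, with curated regulatory domains included, which gave 1 vehicle and 8 progesterone distances beyond 50 kb. The deposited gene tables hold signed distances in bp from the transcription start, and the deposited lists of bound genes that are up or down hold symbols alone.

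Peaks were shared when they overlapped by at least 1 bp. The chance level came from 1000 draws in which each vehicle peak was moved by 10 to 500 kb along its chromosome. Shared and progesterone-only peaks were compared by a two-sided permutation test of mean log2 score with 100000 resamples. The test had been planned on log2 fold enrichment, which the lists used here do not carry, so the score took its place. Shares have exact Clopper-Pearson 95% intervals, the ratio of peak numbers an exact counting interval, and differences of means a bootstrap interval from 2000 draws. Fisher's exact test, two-sided, was used for bound genes, and Benjamini-Hochberg adjustment with a threshold of 0.05 over each family.

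The 11 gene lists, the tests, the settings listed below as planned and the rule for named genes were fixed before the data were examined. The lists were immediate early and NR4A genes, classical progesterone and glucocorticoid response genes, endothelial junction and permeability genes, endothelial identity genes, angiogenic and Notch signalling genes, inflammatory and leukocyte adhesion genes, cell cycle and DNA replication genes, smooth muscle and fibroblast markers, blood cell markers, hepatocyte genes and neuronal genes. The rule named NR4A1, NR4A2 and NR4A3, the 10 peaks of highest score in each final list, the 10 highest shared peaks, the 10 bound up and 10 bound down genes with the highest-scoring peak, and up to 4 bound members per list by the score of their strongest peak. Members without a placed score were taken by distance. List members named beyond this rule were chosen after their values were seen. The reasons were that the authors' deposited tables list them as up or down, that a peak of theirs is in the vehicle list, or, for some hormone response genes, that they had no assigned peak.

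Gene names were matched to a reference table of assembly GRCh38.p14, used for names, protein-coding status, chromosome and order of genes and never for coordinates. For progesterone 3858 of 3882 names matched, 3819 of them protein coding, and 9 of the 24 others had been turned into dates by a spreadsheet. The gene tables do not say which peak a distance belongs to. For the 1195 genes with 2 or more peaks, the spacing of the distances was compared with the spacing of peak centres, with a tolerance of 1 bp, and a gene was placed when a single set of peaks matched. This placed 915 genes, and the 912 of them with a chromosome in the reference all lay on it. The 2687 genes with 1 peak could not be placed, so statements on top scores cover placed genes, and the highest-scoring up and down genes were chosen among them.

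The procedures were tested on simulated data. Of 400 simulated genes 310 were placed, and 310 of these on the right peaks. The simulated distances were taken from the same peak centres, so a single matching set was always the right one. The simulation therefore shows how many genes can be placed and gives no error rate for the deposited distances. The permutation test called 5 of 100 unchanged draws and 100 of 100 draws shifted by 0.25 on the log2 score scale. Among simulated lists of 30 genes, 297 of 300 lists with 60% bound were found and 6 of 800 others were called. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

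Settings tried as planned were a score of at least 100, lists against each control alone, an overlap of 50%, centres within 100 bp, untransformed scores, peaks of at most 1500 bp, binding within 10 kb and medians in place of means for the peaks near changed genes. Others, chosen after the data were seen, were the median log2 score, binding within 5 kb, binding by at least 2 peaks, autosomes alone, assigned distances as the total, progesterone peaks called against any control, the changed genes without list members (bound ones, then also unbound ones taken from the up genes), the strongest peak between genes with 2, 3 or at least 4 peaks or as a mean over a gene's peaks, and peaks per gene in placed genes. Vehicle peaks were compared at equal score within score groups divided at 55, 60, 70 and 100, with a bootstrap interval. Motifs in the peaks were not analysed here, because no genome sequence was used, and promoter, exon and intron classes were not computed for lack of an annotation of the same build.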

Results

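Binding of the progesterone receptor to chromatin was measured by ChIP-seq in primary human umbilical vein endothelial cells (HUVECs), which line the vein of the umbilical cord. The cells had been infected with a lentivirus that carries the human receptor, and were held for 3 days past confluence before receiving 100 nM progesterone for 1 h or vehicle. The series holds 8 libraries with 1 library per group. They are a receptor ChIP with vehicle, a receptor ChIP with progesterone, an IgG control, an uninfected control and 4 inputs. Peak lists were used here for the 2 receptor ChIPs. With no replicates, no difference between the conditions has a replicate error, and the p-values given are for peaks or genes within these libraries, which are not replicates. The deposited lists used here give no read totals, so the depth behind each list is unknown, and the intervals given cover counting error only.

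The first comparison asked where the receptor was bound with and without ligand. With progesterone the final list held 9906 peaks, and with vehicle 525, a ratio of 18.9 (95% counting interval 17.3 to 20.6). The strongest progesterone peak lay at chromosome 6, 2853914 to 2855948 (hg19), with a score of 1988, and was assigned to SERPINB1, which encodes an inhibitor of neutrophil proteases. Peaks at PIGV (chromosome 1, 27070129 to 27071647, score 1238) and PDLIM1, a gene for a cytoskeletal adaptor (chromosome 10, 97032961 to 97033922, score 1182), were also among the 10 highest. The other 7 of these 10 could not be tied to a gene from the deposited tables, the strongest of them at chromosome 17, 71220451 to 71221703 (score 1579), chromosome 12, 122186137 to 122187400 (score 1561) and chromosome 7, 158710333 to 158711329 (score 1392). With vehicle, the PDLIM1 peak (chromosome 10, 97033103 to 97034059) ranked first with a score of 390. A peak at ERG, a transcription factor gene of endothelial cells (chromosome 21, 39870953 to 39871696, score 225), the SERPINB1 peak (chromosome 6, 2854507 to 2855186, score 213) and a peak at DDX47 (chromosome 12, 12937903 to 12938838, score 208) also ranked among the 10 highest vehicle peaks.

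The score is the authors' own value per peak and was used to rank and filter the peaks of each list. Differences in its level between lists are not read as changes in binding. Its median was 72.9 in the vehicle list and 108 in the progesterone list, and the median peak widths were 708 and 822 bp. Each final list was a subset of the peaks called against the control numbered C4. Every final peak also overlapped a peak in the lists against the other 2 controls of its condition, C3 and C5 for vehicle and C3 and C6 for progesterone. The final lists held 32.1% of the vehicle peaks called against C4 and 71.4% of the progesterone peaks. The ratio of progesterone to vehicle peaks depended on the list. It was 8.77 for the lists against C3 alone (12491 and 1424 peaks), 8.48 against C4 (13873 and 1636), 6.79 for C6 against C5 (19921 and 2933), and 45.6 for final peaks with a score of at least 100 (5467 and 120).

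**Figure D1:**
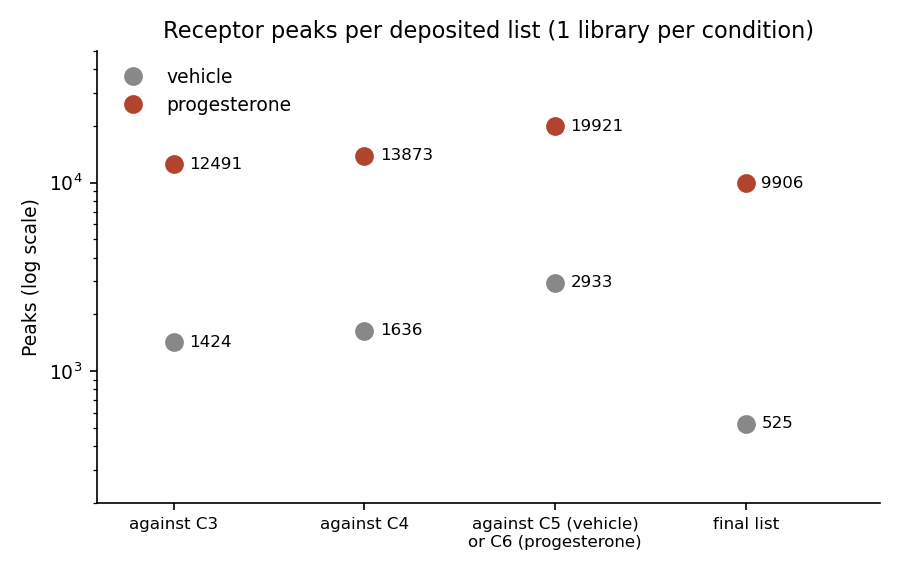
Number of receptor peaks (log scale) in each deposited list, by the control the peaks were called against, for the vehicle (grey) and progesterone (red) libraries, 1 library each. The progesterone lists held 12491, 13873, 19921 and 9906 peaks and the vehicle lists 1424, 1636, 2933 and 525.

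Most sites of the final vehicle list were also in the final progesterone list. Of the 525 final vehicle peaks, 397 (75.6%, exact 95% binomial interval 71.7 to 79.2) overlapped a progesterone peak by at least 1 bp, and these made up 4.01% of the progesterone peaks. All of the 10 highest vehicle peaks were shared, among them those at PDLIM1, ERG, SERPINB1 and DDX47. Of the 10 highest progesterone peaks 7 were shared, while the PIGV peak, the peak at chromosome 7 and a peak at chromosome 11, 86194603 to 86196423 (score 1122), had no overlapping vehicle peak. Other strong shared sites, for which no gene could be placed, lay at chromosome 4, 42341943 to 42342849 (score 1268 with progesterone, 277 with vehicle), chromosome 11, 86270000 to 86271277 (1241 and 182), chromosome 9, 114774004 to 114775517 (1114 and 143), chromosome 19, 18127621 to 18128809 (1102 and 101) and chromosome 16, 69451257 to 69452352 (1051 and 123).

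When every vehicle peak was moved at random by 10 to 500 kb, a mean of 5.64 and at most 15 overlapped a progesterone peak in 1000 draws (permutation of positions, p = 9.99e-04, the smallest these draws can give). The 397 progesterone peaks at shared sites were the same as those of the authors' deposited overlap table. Within the progesterone list, shared peaks had a mean log2 score of 8.24 and the 9509 progesterone-only peaks 6.87, a difference of 1.38 (bootstrap 95% interval 1.28 to 1.48, two-sided permutation p = 1e-05, the smallest 100000 resamples can give). Their median scores were 318 and 105, and 48 of the 100 highest progesterone peaks were shared. Both final lists rest on calls against the controls numbered C4 and C3, and the score is against C4. Score and overlap are therefore not independent measures, and the random shifts do not address this. Among vehicle peaks, those with a score of at least 100 were shared in 120 of 120 cases (lower limit 97.0%) and those with a lower score in 277 of 405 (68.4%). With centres within 100 bp as the criterion, the shared share of vehicle peaks was 47.6%. For the lists against C5 and C6 alone it was 41.0% (1202 of 2933), and of the vehicle peaks called against C4 that the final list left out 43.2% overlapped a final progesterone peak.

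**Figure D2:**
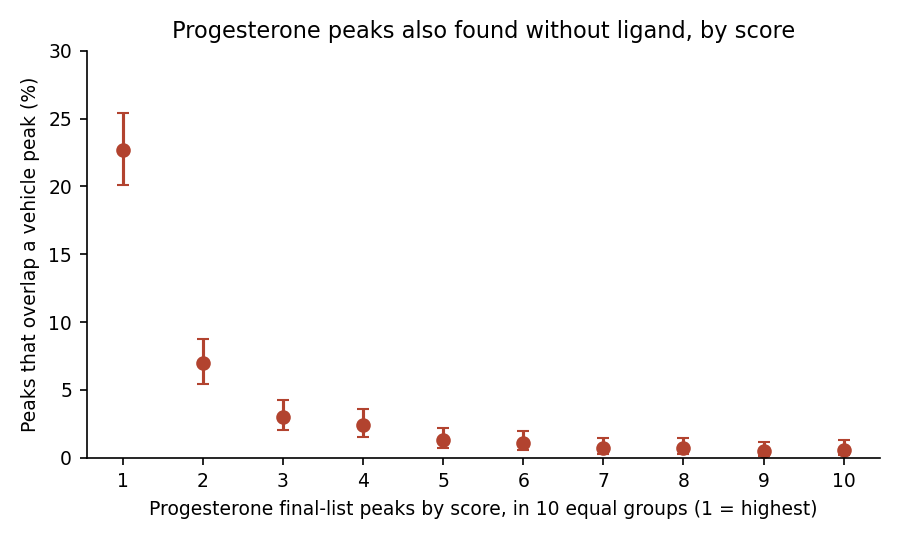
Share of progesterone final-list peaks (%) that overlap a vehicle peak, by score in 10 equal groups from the highest (1) to the lowest (10). Points are shares and bars exact 95% binomial intervals; the highest group stood at 22.7%.

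Progesterone peaks lay closer to gene starts than vehicle peaks did, though in both conditions most were distal. Within 1 kb of the transcription start of their assigned gene lay 5.91% of progesterone peaks and 2.48% of vehicle peaks (odds ratio 2.47, 95% interval 1.42 to 4.70). Examples of progesterone peaks this close were those at CLEC14A (0.017 kb), CXCL8, named IL8 in the deposited tables (0.075 kb), CAV1 (0.104 kb), BMX (0.115 kb) and LYVE1 (0.135 kb), chosen after their values were seen. Within 10 kb the shares were 22.5% and 16.0%, and within 50 kb, the limit of the authors' assignment, 58.0% and 50.7%. The progesterone peaks were assigned to 3882 genes and the vehicle peaks to 261, of which 232 (88.9%) were also bound with progesterone. With progesterone 1195 genes carried 2 or more peaks, and 160 of these at least 4. By Fisher's exact test, two-sided and with Benjamini-Hochberg adjustment over the 4 distances, the adjusted p was 6.24e-04 at 1 kb, 4.05e-05 at 5 kb, 6.24e-04 at 10 kb and 0.00108 at 50 kb. The lists differed in length and strength, and the authors mapped them with different versions of the assignment tool. The test also treats the lists as independent, although 397 of the 525 vehicle peaks overlapped a progesterone peak.

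**Figure D3:**
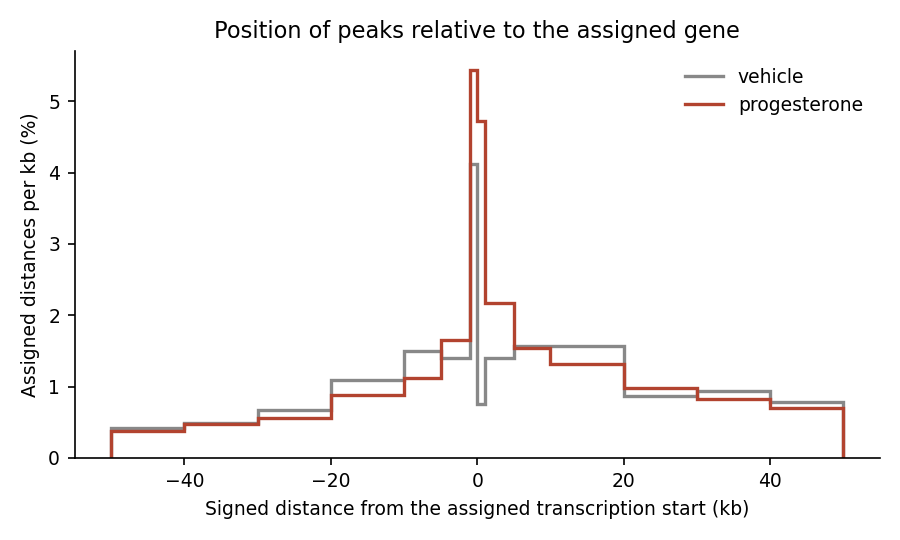
Signed distance (kb) from the transcription start of the assigned gene to each assigned peak, as the percentage of assigned distances per kb, for vehicle (grey) and progesterone (red). Negative values are upstream; 40.7% of progesterone and 44.2% of vehicle distances were upstream.

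NR4A1, the orphan nuclear receptor gene named in the title of the series, had 1 progesterone peak assigned to it, 18.7 kb upstream of its transcription start. No vehicle peak was assigned to it. NR4A2, a gene of the same family, had 1 assigned progesterone peak 0.852 kb downstream of its start and no assigned vehicle peak. NR4A3 had no peak assigned to it in either condition, and peaks near it that were not assigned to it were not searched for. NR4A1 and NR4A2 were listed as up in the authors' deposited table of bound genes. GRASP, which neighbours NR4A1 in the reference annotation, was also listed as up in the authors' deposited table and carried 2 progesterone peaks, at chromosome 12, 52401768 to 52402416 (score 193) and 52418851 to 52419888 (score 121). The next peak along the chromosome lay at 52426129 to 52426907 and had a score of 86.9. The deposited tables give distances without peak names, so the peak assigned to NR4A1 could not be identified by its position.

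The authors' deposited tables of up and down genes name bound genes only. Their labels also carry the numbers 431 for down and 406 for up, and the shares given here rest on reading these as all genes that changed in that direction. On that reading down genes were bound more often than up genes. Of the down genes, 49.7% of 431 (interval 44.8 to 54.5) had a progesterone peak assigned to them within 50 kb. For the up genes this share was 22.9% of 406 (18.9 to 27.3), beside 19.0% of 20056 protein-coding genes. Each peak was assigned to its nearest gene, so at every distance a peak nearer to another gene did not count. The odds ratio of down to up was 3.32 (95% interval 2.44 to 4.53, Fisher's exact test, two-sided, p = 6.18e-16). At shorter distances it was lower, with 2.67 (1.85 to 3.86) within 10 kb, 2.32 (1.55 to 3.52) within 5 kb and 1.89 (1.09 to 3.35) within 1 kb. Against protein-coding genes the same exact test gave an odds ratio of 4.38 for the down genes (p = 1.36e-47) and 1.27 for the up genes (0.994 to 1.61, p = 0.0478). By the same exact test the up genes gave 1.55 (1.14 to 2.08, p = 0.00411) within 10 kb, 1.71 (1.21 to 2.37, p = 0.00216) within 5 kb and 2.09 (p = 0.00208) within 1 kb.

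Among genes listed as down in the authors' deposited table, the strongest placed peak was at BMX, a tyrosine kinase gene active in endothelium (chromosome X, 15533963 to 15534618, score 1048). VPS37B (chromosome 12, 123372804 to 123373397, score 970), SDPR, a caveolar protein gene (chromosome 2, 192711008 to 192712419, score 713), SEC14L2 (score 709) and AGFG2 (score 650) followed. DUSP6, which encodes a phosphatase of ERK kinases (chromosome 12, 89769191 to 89770573, score 641), PRKCH, a protein kinase C gene (score 601), EHD4 (score 576), TEX2 (score 552) and LMO2, a gene for a transcription cofactor of blood and vessel development (score 516), completed the 10. The peaks at BMX, VPS37B, SDPR, SEC14L2, AGFG2, PRKCH and TEX2 overlapped vehicle peaks, and those at DUSP6, EHD4 and LMO2 did not. Among genes listed as up in the authors' deposited table, WEE1, which encodes an inhibitory kinase of the cell cycle (chromosome 11, 9634394 to 9635737), had the strongest placed peak, with a score of 544. NPAS1 (score 528), GRHL1 (score 365) and MAFF, a small Maf factor gene (score 303), followed, then GRASP (193), USP12 (173), ELL2 (172), ARHGAP31 (167), KLHL21 (162.5) and MEIS2 (162). Of these 10 peaks in up genes, the peak at NPAS1 overlapped a vehicle peak and the others did not.

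The down genes also carried more peaks each. They had a mean of 1.96 ± 1.22 peaks (SD, over the bound down genes) and the up genes 1.39 ± 0.708 (SD, n = 93 genes), a difference of 0.576 (bootstrap 95% interval 0.355 to 0.791, permutation p = 3.00e-05, adjusted p = 9.00e-05 over 3 measures). Among all bound genes, the share listed as down in the authors' deposited table was 3.72% of genes with 1 peak, 7.96% with 2, 9.84% with 3 and 16.9% with at least 4. The shares listed as up in the authors' deposited table were 2.42%, 2.91%, 1.23% and 1.25%. The log10 distance to the nearest peak did not pass the test (difference 0.01, interval -0.18 to 0.21, permutation p = 0.895). The strongest peak was higher in down than in up genes by 0.52 on the log2 score scale (0.14 to 0.91, permutation p = 0.0192, adjusted p = 0.0288), over the 93 down and 19 up genes whose peaks could be placed. These had 2.99 and 2.42 peaks each, and a maximum rises with the number of peaks. Between genes with equal numbers of peaks the difference was 0.41 and did not pass the test (permutation p = 0.0783), and in the mean score over a gene's peaks it was 0.38 (0.16 to 0.59, permutation p = 0.0153). The difference in peaks per gene did not pass the test when medians were compared (2 and 1 peaks, permutation p = 0.213) or in placed genes alone, where it was 0.568 (0.123 to 0.985, permutation p = 0.0569) for all peaks and 0.462 (permutation p = 0.116) for peaks with a score of at least 100. Placed genes all have at least 2 peaks, as did 53.3% of bound down and 30.1% of bound up genes. They therefore leave out the difference in that share and do not retest the difference over all bound genes. How and in which cells the authors measured the change of these genes is not given in the sources used here.

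Of 11 gene lists fixed in advance, 6 were bound more often than other protein-coding genes. They were the immediate early, classical hormone response, endothelial junction, endothelial identity, angiogenic and inflammatory lists, and of their 166 different genes 104 (62.7%) were bound. Lists share members, and 10 genes stood in more than 1 of the 11. Members listed as down or up are named below, but their numbers were not tested against all bound genes. Of all 3882 bound genes 93 were listed as up. The share listed as down ran from 3.72% of bound genes with 1 peak to 16.9% with at least 4. Fisher's exact test, two-sided, was adjusted by Benjamini-Hochberg over the 11 lists. The other protein-coding genes were taken whether or not they are expressed in these cells, and expression was not used. The test therefore cannot tell binding that favours these lists from binding near expressed genes of any kind. The 6 lists also passed within 10 kb, where the odds ratio fell from 9.33 to 4.52 for the angiogenic and from 15.4 to 9.05 for the immediate early list.

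The immediate early and NR4A genes, a class of rapidly induced regulators, were bound in 18 of 23 cases (78.3%, odds ratio 15.4, Fisher's exact adjusted p = 4.81e-09). DUSP1, a gene for a MAP kinase phosphatase, had 3 peaks with a top score of 555, KLF6 had 6 (362.5), KLF2, a flow-responsive transcription factor gene, had 5 (331) and IER3 had 3 (294). KLF2, IER3, JUN, MYC, KLF4 and DUSP5 were listed as down in the authors' deposited table, and NR4A1, NR4A2 and JUNB as up. No bound member of this list had an assigned vehicle peak. Of the classical progesterone and glucocorticoid response genes, 13 of 30 were bound (43.3%, odds ratio 3.26, Fisher's exact adjusted p = 0.00358). Besides DUSP1 the strongest were MT2A, a metallothionein gene (2 peaks, top score 394), KLF9 (4 peaks, 273) and ERRFI1, a feedback inhibitor gene of the EGF receptor (2 peaks, 162). Members with no assigned peak included FKBP5, TSC22D3, ZBTB16, SGK1, HSD11B2 and GREB1. Since 58.0% of progesterone peaks were assigned to a gene within 50 kb, a missing assignment does not show that the receptor was not bound at these genes. ERRFI1 and IRS2 were listed as down and BCL6 as up in the authors' deposited table, and 5 of the 13, MT2A, KLF9, PER1, CEBPD and STAT5A, also had a vehicle peak.

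Junction and permeability genes of endothelium were bound in 20 of 30 cases (66.7%, odds ratio 8.54, Fisher's exact adjusted p = 4.27e-08). The highest scores belonged to AMOTL1, a gene for a junction-associated angiomotin (1004), PTPRB, the vascular endothelial protein tyrosine phosphatase gene (439), S1PR1, a gene for a sphingosine-1-phosphate receptor (413), and ROBO4, an endothelial guidance receptor gene (263). PTPRB, ROBO4, CLDN5, F11R and ICAM2 were listed as down in the authors' deposited table and no member as up. With 93 of all 3882 bound genes listed as up, the absence of up genes among these 20 shows no direction. Endothelial identity genes were bound in 24 of 34 cases (70.6%, odds ratio 10.3, Fisher's exact adjusted p = 9.47e-10). ERG had 6 peaks (top score 898), EGFL7 had 4 (623), LYVE1 had 4 (438) and FLT1, a VEGF receptor gene, had 2 (387). LYVE1, ROBO4, TEK and CLEC14A were listed as down and PROX1, a regulator of lymphatic identity, as up in the authors' deposited table.

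Angiogenic and Notch signalling genes were bound in 24 of 35 cases (68.6%, odds ratio 9.33, Fisher's exact adjusted p = 1.23e-09). EPAS1, a gene for a hypoxia-inducible factor, had 4 peaks (top score 576), ESM1 had 2 (491), FLT1 had 2 (387) and VEGFC had 2 (234). ESM1, VEGFC, SMAD6, PGF, TEK, ID3, DLL4, NOTCH1 and HES1 were listed as down and UNC5B as up in the authors' deposited table. Inflammatory and leukocyte adhesion genes were bound in 12 of 23 cases (52.2%, odds ratio 4.65, Fisher's exact adjusted p = 8.12e-04). NFKBIA, which encodes an inhibitor of NF-kappa-B, had 3 peaks (443). The chemokine genes CXCL8, CXCL2 and CCL20 had 2 (386), 3 (377) and 2 (304). CXCL8, CXCL2, IL6, VCAM1 and PTGS2 were listed as down in the authors' deposited table and no member as up. Few bound genes were listed as up at all, so the absence of up genes among these 12 shows no direction.

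The other 5 lists did not pass the test. Cell cycle and DNA replication genes were bound in 5 of 38 cases (odds ratio 0.644, Fisher's exact adjusted p = 0.609), CDKN1A, CDC6, CDK6 and CCNE2 among them. Markers of cells that an umbilical vein culture could also hold were bound in 4 of 18 cases for smooth muscle and fibroblasts (FAP, RGS5, COL1A1 and COL1A2, odds ratio 1.21, Fisher's exact adjusted p = 0.763) and 2 of 18 for blood cells (CD3E and CD14, 0.531, adjusted p = 0.609). Genes of cell types outside the culture were bound in 2 of 27 cases for hepatocytes (APOA1 and G6PC1, odds ratio 0.340, Fisher's exact adjusted p = 0.229) and 2 of 25 for neurons (TUBB3 and SYN1, 0.369, adjusted p = 0.283). Genes that the authors' assignment tool did not know count as unbound here, and the intervals of these lists are wide.

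**Figure D4:**
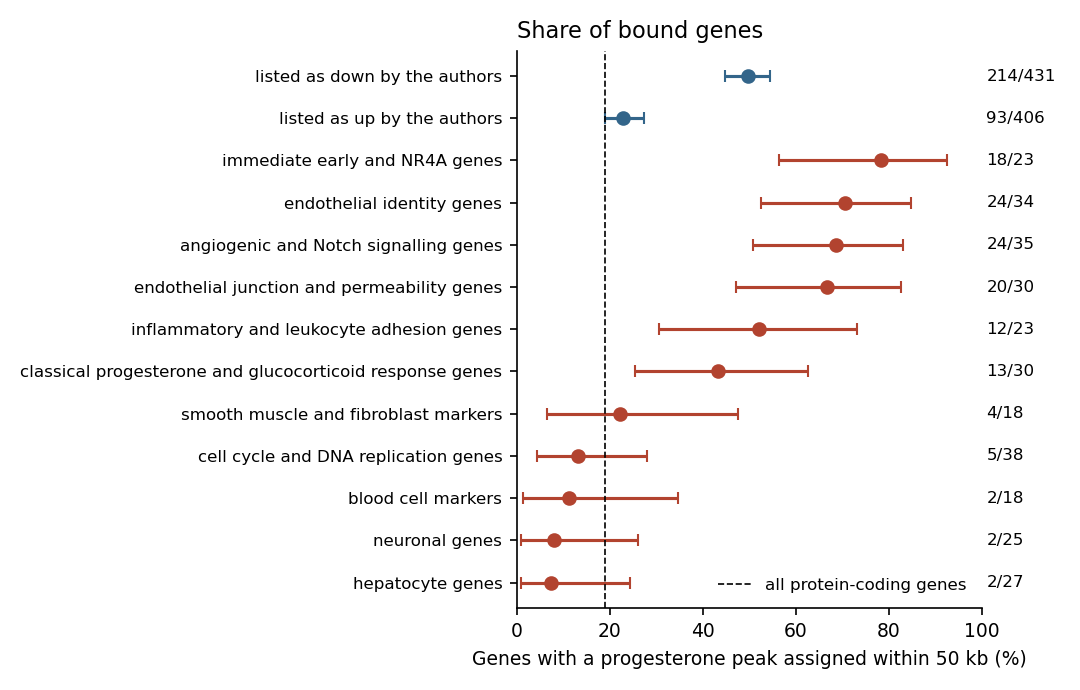
Share of genes (%) with a progesterone peak assigned within 50 kb, for the genes listed as down or up in the authors' deposited tables (blue) and the 11 fixed gene lists (red), with exact 95% binomial intervals and bound genes over all genes at the right. The blue shares rest on reading 431 and 406 as all genes that changed, since the tables name bound genes only. The dashed line marks the 19.0% of protein-coding genes that were bound; 6 of the red lists lay above it by Fisher's exact test.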

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

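Medians for the strength test, binding within 5 kb or by at least 2 peaks, autosomes alone, assigned distances as the total, progesterone peaks called against any control, the changed genes without list members, the strongest peak at equal numbers of peaks or as a mean, and peaks per gene in placed genes were chosen after the data were seen. Over 22 results and 50 alternative values, 36 kept their direction and side of the threshold or moved within their interval, 9 moved, 4 no longer passed the test and 1 reversed. The ratio of progesterone to vehicle peaks moved from 18.9 to 45.6 with a score of at least 100, and to 8.77, 8.48 and 6.79 for lists against C3, C4, and C6 with C5 alone. The shared share of vehicle peaks moved from 75.6% to 47.6% with centres within 100 bp, 100% at a score of at least 100 and 41.0% for the lists against C5 and C6. The share within 10 kb became 31.5% (vehicle) and 38.8% (progesterone) with assigned distances as the total, by construction. The difference in peaks per gene between down and up genes did not pass the permutation test as a median (difference 1, p = 0.213) or in the 93 and 19 placed genes, be it for all peaks (0.568, p = 0.0569) or those with a score of at least 100 (0.462, p = 0.116). Placed genes all have at least 2 peaks, so their values cannot be set beside the 0.576 of all bound genes. The difference in the strongest peak went from 0.52 to 0.41 between genes with equal numbers of peaks (permutation p = 0.0783). Calls kept with a much changed odds ratio were angiogenic (9.33 to 4.52), immediate early (15.4 to 9.05) and neuronal genes (0.369 to 0.854) within 10 kb, and with 2 peaks endothelial identity (10.3 to 18.3), inflammatory (4.65 to 7.05) and smooth muscle genes (1.21 to 2.00), with blood and neuronal genes at 0. The odds ratio of hepatocyte genes went from 0.340 to 1.28 when 2 peaks were required, on 2 bound genes and past no threshold in either case. Apart from the constructions named, the cause was not tested. Planned settings on fold enrichment, tag counts, the false discovery rate, summits, motifs, an unbound background from the files, and distances or gene lists at a score of at least 100 were not run, because the files used here lack these values or do not link single peaks to genes. Unknown depth limits each ratio between conditions.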

Other observations

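Tests chosen only after the result was seen were those of strong sites among the shared peaks, of scores among vehicle-only peaks, of peaks per gene against other bound genes, of vehicle peaks called against C4 alone, of changed genes with unbound list members taken from the up genes, and the values on clustering and on vehicle peaks at changed genes. The tests of changed genes within 5 kb and without list members were added after the files had been seen, but before their values were known.

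Progesterone peaks gathered around some genes. HSPG2, which encodes the basement membrane proteoglycan perlecan, had 10 peaks between chromosome 1, 22226272 and 22282361, with a top score of 325. TGM2, a transglutaminase gene, had 8 (top score 899), SEC14L1 had 8 (332), SPARC, a matrix protein gene, had 7 (228), ECE1, the endothelin-converting enzyme gene, had 7 (416), and PXN, the gene for the focal adhesion protein paxillin, had 7 (598). SHH also had 10, but these reached to -797 kb from its start, through the curated domain of the assignment tool. Of the 23 genes with at least 6 peaks, SEC14L1 and SH2B3 were listed as down in the authors' deposited table and none as up. With 93 of all 3882 bound genes listed as up, the absence of up genes among these 23 shows no direction. Another peak lay within 10 kb of 27.2% of progesterone peaks, against a mean of 12.8% over 100 random shifts.

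Some genes listed as changed in the authors' deposited table already carried a vehicle peak. They were 23 of the bound down genes (10.7%), such as BMX, PRKCH, SDPR, ESM1, PLAT, the tissue plasminogen activator gene, and CXCL8, and 3 of the 93 bound up genes (3.23%), NPAS1, PDK4 and STX11. The nearest vehicle peak lay 44.3, 46.3 and 40.4 kb from the starts of NPAS1, PDK4 and STX11. Among the down genes this distance ran from 0.052 kb (SDPR) to 48.6 kb (NR5A2), with 35.7 kb for CXCL8. The odds ratio of down to up was 3.61 (1.05 to 19.2, Fisher's exact test, two-sided, p = 0.0422), and that of down to the other bound genes 1.99 (1.21 to 3.16, p = 0.00458). Down genes also carried more progesterone peaks each than up genes (means 1.96 and 1.39), which these odds ratios do not take into account. The progesterone gene table also holds a second list of 251 different symbols without distances. It includes 92 of the 93 up genes, all but CCNO, none of the down genes, and 22 symbols that start with PLEK.

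The progesterone library had more peaks in each pair of lists, yet the ratio moved between 6.79 and 45.6. Of the vehicle peaks called against C4, those the final list kept overlapped a progesterone peak more often than those it left out, by 32.4 percentage points (75.6% and 43.2%), but their median scores also differed (72.9 and 56.6). Most left-out peaks were in another vehicle list too, so this decides little on calls against a single control. At equal score, peaks in all 3 vehicle lists exceeded the 441 in the C4 list alone by 16.6 points (8.84 to 24.6). The ratio of progesterone to vehicle peaks was 1.68 among peaks in the C4 list alone. It was 4.74 among C4 peaks in 1 other list and 18.9 among those in all 3. Calls against C4 alone (441 vehicle and 743 progesterone peaks) thus lowered the ratio of the C4 lists (8.48). So did the larger group of C4 peaks in 1 other list (667 and 3160). Whether any of these calls are false, and whether the same holds for the lists against other controls, stays open. A difference in read depth stays open, because none (0) of the files used here gave a read total, so depth and treatment cannot be told apart for the number of peaks, and an effect of the ligand, which the design names, stays open too.

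The overlap of vehicle and progesterone sites was not what wide peaks give by chance, since at most 15 of the shifted vehicle peaks overlapped where 397 did. The shared sites were concentrated among strong progesterone sites, with the shared share among the highest 10% of scores 31.2 times that in the lower 50%. Of that highest 10%, 77.3% had no vehicle peak. With 991 peaks in this group and 397 shared peaks in the whole list, most of the group would lack a vehicle peak in any case. That share therefore cannot decide whether vehicle detection was limited to strong sites, which stays open. Of the 128 vehicle-only peaks, 118 were in no progesterone list, so the rule of 3 controls does not account for those, and for the other 10 it stays open. The vehicle-only peaks had a median score of 57.4, beside 81.8 for shared peaks, and none (0) reached 100, which explains nothing further because it restates that all vehicle peaks of such a score were shared.

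On the reading of 431 and 406 as totals, genes listed as down in the authors' deposited table were bound more often than those listed as up. Wide intergenic space around the down genes, which would gather distal peaks, does not account for all of it. The odds ratio of down to up was 2.32 (1.55 to 3.52) within 5 kb, though it fell from 3.32 at 50 kb to 1.89 within 1 kb. Against protein-coding genes the down genes stood at 4.38 within 50 kb and 4.12 (2.91 to 5.71) within 1 kb, and the up genes at 1.27 and 2.09. The fall in the down to up odds ratio thus went with the up genes, and whether a part comes from distal peaks stays open. The odds ratio was 3.07 (2.23 to 4.22) without the bound members of the vascular, immediate early and inflammatory lists, 27 down and 5 up, the only ones the files name, and 2.62 (1.90 to 3.63) if all 45 unbound members were up genes, so these lists alone do not account for it either. Down genes had 0.508 more peaks each than the other bound genes (0.336 to 0.689, permutation p = 1e-05, the smallest possible), while up genes differed by -0.0977 (p = 0.332), which restates the pattern and explains nothing. How the authors chose the genes, and whether both classes were expressed alike in these cells, stays open and untested.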
